A study of Homo sapiens with 9 samples.

How the data were processed

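The data are the deposited value table of 9 microarrays, with 1 array per sample. Per the labels' protocols, total RNA was extracted, and labelled copy RNA was made with the dye Cy3 from 0.5 µg of RNA for single-colour Agilent arrays. Agilent Feature Extraction 10.7.1.1 is named in the submitters' processing notes. The authors deposited log2 intensities: the base is not stated and was taken from the range of the values, 1.31 to 18.9. The 9 deposited columns share the same minimum, maximum, mean and median (5.38), as quantile normalization between arrays gives; the tool that did this, any background correction and any filter on probes are not given in the sources used here. Such a normalization forces every array to one distribution, so a change common to most probes cannot be seen, and a difference in background between arrays is spread over the dim probes. Each ID occurs only on 1 row, so repeated spots had been combined or left out before deposit. Detection flags and scanner values were not used here.

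The 163952 rows whose IDs begin with hsa_ were tested, and 68 array control features were set aside. The files do not pair probe IDs with genes. The IDs were looked up in the gene tables by gene ID, symbol, synonym and transcript accession, and 0 matched. The design, fixed before the data were examined, was to test 1 probe per gene symbol and provided for a fit on all probes if none could be named. That fit on all probes is the main result, and the gene-level rows, the target genes and the 26 gene lists were not run. For the same reason the rule for named items reduces to its last clause: the 2 largest rises and 2 largest falls among called probes in each comparison, by ID. ID prefixes are reported as they stand.

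Groups came from the sample titles. The labels call the replicates biological; they do not say whether arrays share a slide, day or batch. One linear model with 3 group means was fitted to the 9 arrays with limma 3.58.1 (lmFit and eBayes, 6 residual degrees of freedom, R 4.3.3), and the 3 contrasts were taken from it. Values were not normalized again. A probe was called, and is said to have risen, fallen or changed, where the Benjamini-Hochberg adjusted p over all tested probes was under 0.05; counts at 2-fold or more are given beside. Errors are standard deviations over 3 replicates, or limma's standard errors for fold changes. Where every array of the dim group lay at or below the higher of the 2 negative control features, DarkCorner and (-)3xSLv1, the fold is given as a lower bound. Where only some of its arrays did, the fitted fold change is given with such a bound beside it. Probe prefixes were compared with 10000 random draws of equally bright probes in 20 bins of mean level, and as sets with camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the 8 prefixes. Control features were fitted together with all rows and adjusted over the 68. Exact permutation tests are two-sided and 3 against 3 arrays cannot go below 0.1.

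The same fit was tested on simulated data for the 163952 probes, drawn with the real means and spreads, with known changes given to probes of the brighter 50%. In the EGFR knockdown comparison it recovered 66.2% of the simulated 2-fold changes and 92.5% of those of 2 log2 units, and in the E-cadherin comparison 53.8% and 95.0%. It also called 8 and 15 unchanged probes in these comparisons, and where no probe had a change it called 0 in each. The simulated noise was independent between probes and arrays, with the same spread in every group. The deposited arrays also differ as wholes and neighbouring probes move together, so these rates need not hold for them.

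Alternatives fixed before the data were examined were a repeated quantile normalization, a shift to equal 75th percentiles, leaving out the lowest 25% or 50% of probes by mean level, eBayes with trend and robust, array weights, a fit on only the groups compared, the replicate number as a block, an adjusted p under 0.01, and leaving out each array in turn. The same alternatives planned on gene level, for the target genes and for the gene lists, and the mean over several probes of a gene, were not run. Chosen after seeing the data were a covariate made from the leading component of the control features, a floor at the highest DarkCorner level, and leaving out control replicate 3 and E-cadherin replicate 3 together. The replicate numbers were checked as pairs on the brighter 50% of the probes: of 9 pairs of same-numbered arrays in different groups, 1 had residuals that correlated over 0.1 (range -0.121 to 0.165), so the numbers were not taken to pair the arrays. The covariance of the fold changes was also computed with a different control array in each comparison, which was chosen after seeing the data. Unchanged groups against shared controls were simulated 100 times by reordering the arrays' residuals with random sign. Figures were drawn with matplotlib 3.10.9.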

Results

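RNA of AGS cells, a human gastric adenocarcinoma cell line, was profiled on 9 single-colour microarrays in 3 groups of 3 biological replicates: control cells, cells with EGFR knocked down by small interfering RNA, and cells overexpressing E-cadherin. EGFR is the receptor tyrosine kinase for epidermal growth factor, and E-cadherin is the adhesion protein of epithelial junctions, encoded by CDH1. Transfection lasted 6 hours and the cells were used after a further 36 hours. The series asks which genes are regulated by both in the growth and spread of gastric cancer cells, with attention to networks of competing endogenous RNAs, transcripts thought to compete for shared microRNAs. The table held 164020 features, of which 163952 were probes for human transcripts and 68 were array control features, and its values were log2 intensities from 1.31 to 18.9. The number of arrays limits the precision of every value. The files do not pair the probe IDs with genes, and the IDs matched 0 entries of the gene tables used, so EGFR, CDH1 and the 26 gene lists chosen for these cells were not analysed here, and the effect of each manipulation on its own target was not checked. Probes are therefore described by ID, by the prefix of the ID and by brightness. The labels describe 1 control group while the protocol lists separate negative controls for the interfering RNA and for overexpression, so which transfection the control cells received is not settled.

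On the brighter probes the arrays separated by group. Over the brighter 50% of the probes, component 1 placed the E-cadherin arrays at 65.9 to 79.0 and all control and EGFR knockdown arrays at -52.9 to -13.6. Component 2 placed the controls at 9.19 to 69.9 and the EGFR knockdown arrays at -41.3 to -26.6. These components held 49.1% and 23.6% of the variance. Control replicate 3 was the control nearest to the knockdown arrays: its correlation with them, after centring each probe, was 0.160 to 0.235, against 0.125 and 0.104 with control replicates 1 and 2. Over all probes the order differed. Component 1 then put E-cadherin replicates 1 and 2 at 204 and 187 but replicate 3 at -100, with control replicates 1, 2 and 3 at -131, -69.7 and -54.9 and knockdown replicates 1, 2 and 3 at 93.9, -142 and 11.7. The DarkCorner feature, a negative control, read 1.54 or less on E-cadherin replicates 1 and 2, 2.35 on replicate 3 and 2.31 on control replicate 1, and between 9.41% and 22.5% of probes per array lay at or below the higher of the 2 negative control features. Across the 9 arrays component 1 fell as the DarkCorner level rose, with Pearson's r = -0.886 (exact permutation p = 0.0021, two-sided) and Spearman's rho = -0.867 (exact permutation p = 0.0045). Without the 2 arrays farthest from the median DarkCorner level r was -0.892, and within groups it was -0.960 (exact permutation p = 0.0046 over 216 orders). This was the 1 relation of its kind computed, and it was chosen after the components were seen. The within-group p is the smallest that 216 orders allow, and the tests over 9 arrays treat arrays of different groups as exchangeable. The DarkCorner level was read from the same normalized values as the probes, so it is not an independent measure of background.

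**Figure D1:**
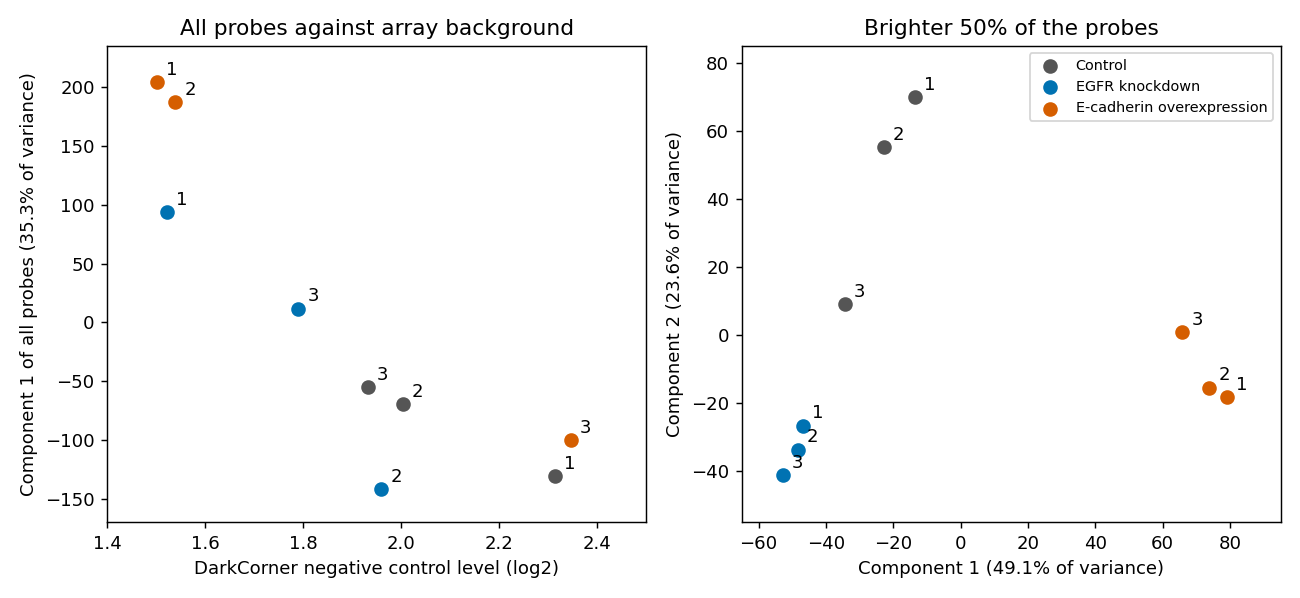
Left, component 1 of all probes (arbitrary units) against the log2 level of the DarkCorner negative control feature. Right, components 1 and 2 of the brighter 50% of the probes; each point is 1 array, coloured by group and numbered by replicate. On the left E-cadherin replicate 3 lies at -100 and the other E-cadherin arrays at 187 and 204, and on the right the 3 E-cadherin arrays lie together at 65.9 to 79.0.

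After EGFR knockdown fewer probes passed than in the other comparisons, and more of them were lower than higher when all 9 arrays were used. Against control, 1552 of the 163952 probes (0.947%) passed an adjusted p of 0.05 in limma, 495 higher and 1057 lower after knockdown, and 483 of them differed at least 2-fold, 136 higher and 347 lower. The median size of the called changes was 0.79 on the log2 scale. The largest rise was that of hsa_gmr066665, from 4.39 ± 0.58 to 7.50 ± 0.07 (mean log2 intensity ± SD, n = 3), a log2 fold change of 3.11 (SE 0.39, adjusted p = 0.024), while it read 4.06 ± 0.69 after E-cadherin overexpression. Next was hsa_bnc056249, which was at or below the negative controls on all 3 control arrays (1.4 ± 0.03) and read 4.46 ± 0.51 after knockdown, at least 5.21-fold higher (adjusted p = 0.0087). That bound sets the knockdown mean against the higher of the probe's own value and the negative controls on each control array. The largest falls were those of hsa_gnc123373, from 5.58 ± 0.06 to 2.39 ± 0.99 (log2 fold change -3.20, SE 0.44, adjusted p = 0.032), and hsa_gnc149469, from 5.73 ± 0.36 to 2.63 ± 0.64 (log2 fold change -3.10, SE 0.34, adjusted p = 0.016). No probe passed with a change of 32-fold in either direction. All 1552 called probes had knockdown values that did not overlap the control values, which their selection by a small p made likely. So had 23.3% of all probes, where chance gives 10% on average. Probes that move together on an array can shift that share, so by itself it is no sign of a treatment effect. The count depended on the arrays and settings used: it was 10108 without the lowest 50% of probes, 3549 without the lowest 25%, 7781 with a trended, robust variance, 5994 with the floor at the negative controls, 4764 with array weights and 538 with the control-feature covariate, and it was 253, 561 and 5297 without control replicate 1, 2 or 3, 324, 453 and 184 without knockdown replicate 1, 2 or 3, and 473, 369 and 830 without E-cadherin replicate 1, 2 or 3. Without control replicate 3 the calls were 2701 higher and 2596 lower, with only the control and knockdown arrays in the fit 2 probes passed, and the 4 named probes, in the order given, lost their call in 9 of 21, 3 of 19, 12 of 20 and 5 of 20 alternatives (adjusted p up to 0.127). At an adjusted p under 0.01, 165 probes passed, and with the replicate number as a block, which did not pair the arrays, 0 passed.

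After E-cadherin overexpression more probes passed than after EGFR knockdown, and their changes reached larger sizes. Against control, 16669 probes (10.2%) passed, 7905 higher and 8764 lower, and 4306 of them differed at least 2-fold, 1820 higher and 2486 lower. The median called change was 0.62 on the log2 scale. The largest rises were on hsa_gnc132245, from 2.01 ± 0.41 to 8.52 ± 0.03 (log2 fold change 6.52, SE 0.22, adjusted p = 6.43e-05), and hsa_gnc132247, from 2.21 ± 0.53 to 8.31 ± 0.07 (log2 fold change 6.09, SE 0.30, adjusted p = 0.00016). In controls these probes were at or below the negative controls on 2 and 1 of the 3 arrays, and with the negative control level in place of lower values they were at least 77.8-fold and 64.0-fold higher with E-cadherin. After EGFR knockdown they read 1.91 ± 0.28 and 1.82 ± 0.43. In total 7 probes rose at least 32-fold. Those among them that already lay above the median level in control cells, a condition chosen after the values were seen, read 7.80 to 7.95 on the control arrays, 7.82 to 8.11 on the knockdown arrays and 13.4 to 13.8 on the E-cadherin arrays, and their highest adjusted p was 2.18e-06. The largest falls were on hsa_bmr034769, from 8.85 ± 0.17 to 2.71 ± 1.29 (log2 fold change -6.14, SE 0.57, adjusted p = 0.0014), with 6.67 ± 0.24 after EGFR knockdown, and hsa_gmr034610, from 6.33 ± 0.33 to 1.85 ± 0.57 (log2 fold change -4.49, SE 0.29, adjusted p = 0.00039). Each was at or below the negative controls on 1 of the 3 E-cadherin arrays, and taken against that level the falls were at least 64.3-fold and 21.6-fold. All 16669 called probes had non-overlapping groups, as had 31.5% of all probes, where chance gives 10% on average, with the limits given for knockdown. The count was 27129 with array weights (8308 at 2-fold or more) and 8517 with only the groups compared, 1988 probes passed at 2-fold or more without the lowest 50% of probes, and leaving out 1 array gave 7652 to 17783 calls, with moves of more than 1.5 times without E-cadherin replicate 1 (7658) or 2 (7652) and without control replicate 1 (9422) or 2 (9681). Without E-cadherin replicate 3, which stood apart over all probes, 17783 passed, 7936 higher and 9847 lower, and the count at 2-fold or more was 8171, against 2840 and 2801 without replicate 1 or 2; with the control-feature covariate rises outnumbered falls, 6923 to 5565.

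**Figure D2:**
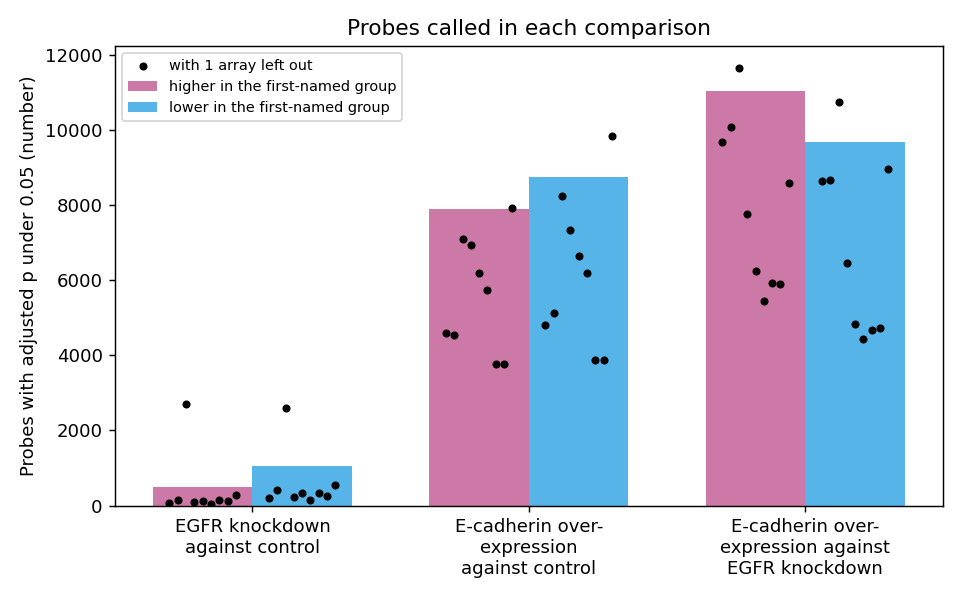
Number of probes with an adjusted p under 0.05 in each comparison, higher or lower in the group named first. Bars show the fit on all 9 arrays and black points the fits with 1 array left out; the EGFR knockdown comparison has 495 and 1057 calls and the other comparisons between 7905 and 11039 per direction.

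The direct comparison of E-cadherin overexpression with EGFR knockdown, which sets the treated groups against each other without the control arrays as a reference, gave more calls than either comparison against control when all 9 arrays were used. In it 20719 probes (12.6%) passed, 11039 higher and 9680 lower with E-cadherin, and 4452 differed at least 2-fold, 1941 higher and 2511 lower. The largest rises were again on hsa_gnc132245 (log2 fold change 6.61, SE 0.22, adjusted p = 3.32e-05) and hsa_gnc132247 (log2 fold change 6.49, SE 0.30, adjusted p = 0.00011). The latter was at or below the negative controls on 2 of the 3 knockdown arrays, and taken against that level it was at least 83.2-fold higher. The largest falls were on hsa_gmr023907, which read 8.77 ± 0.10 after knockdown and 2.95 ± 0.45 with E-cadherin (log2 fold change -5.82, SE 0.22, adjusted p = 5.4e-05), and hsa_gmr077411, at 8.59 ± 0.15 and 3.01 ± 0.24 (log2 fold change -5.59, SE 0.17, adjusted p = 2.52e-05). In control cells both lay between, at 6.79 ± 0.21 and 6.63 ± 0.25. All 20719 called probes had non-overlapping groups, as had 34.5% of all probes, where chance gives 10% on average, with the same limits. The count was 37462 with array weights (8691 at 2-fold or more), 2649 passed at 2-fold or more without the lowest 50% of probes, and leaving out 1 array gave 9887 to 22423 calls, where the moves of more than 1.5 times came without knockdown replicate 2 (11106) or 3 (9887) and without E-cadherin replicate 1 (10621) or 2 (10646). Without knockdown replicate 1, 2 or 3 the direct comparison had fewer calls (14225, 11106 and 9887) than E-cadherin against control (14306, 12838 and 11940), as it had without E-cadherin replicate 3 (17549 against 17783), where falls outnumbered rises, 8959 to 8590, as they did without control replicate 3 and E-cadherin replicate 3 together (9954 to 8962).

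**Figure D3:**
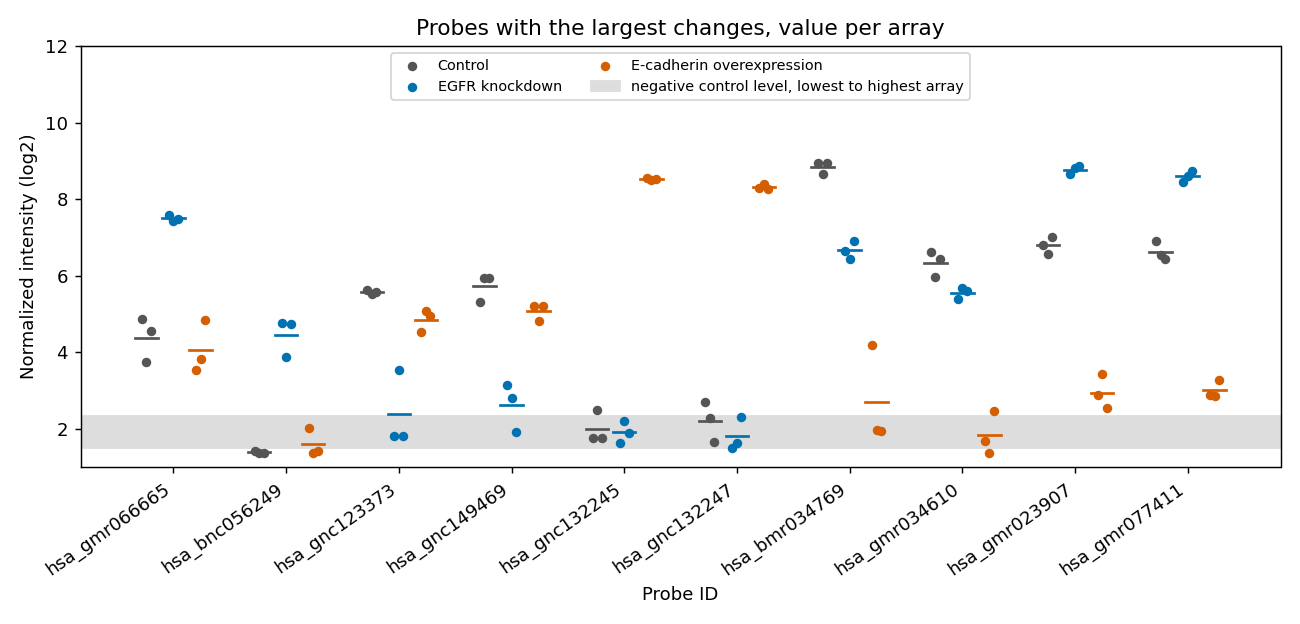
Normalized log2 intensity on each array (points) and group mean (lines, n = 3) of the probes with the largest changes, 2 rises and 2 falls per comparison. The grey band spans the negative control level of the 9 arrays; hsa_gnc132245 and hsa_gnc132247 lie in or near it in control and knockdown cells and at 8.31 to 8.52 on average with E-cadherin.

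The series is built around transcripts that respond to both manipulations. In total 863 probes passed in both comparisons against control, which is 55.6% of the knockdown calls: 140 rose in both, 467 fell in both, 84 rose with knockdown and fell with E-cadherin, and 172 fell with knockdown and rose with E-cadherin. So 607 moved the same way and 256 opposite ways. Independent lists of these sizes would share 23.9, 56.5, 26.5 and 51.0 probes in the same order. As a baseline these numbers are too low, since both lists come from the same fit with the same spread per probe. Both also lie mainly in the brighter 50% of the probes, which held 1332 of the 1552 knockdown calls and 13475 of the 16669 E-cadherin calls. The opposite directions exceeded the baseline too. Of all 863 probes called in both, in any direction, 234 changed at least 2-fold in both comparisons. Both comparisons use the same 3 control arrays. In 100 simulations of unchanged groups against shared controls, built from the arrays' own residuals, 0 probes passed in both. Without any change the fit calls almost no probe in either comparison. This 0 therefore does not tell how many would be shared where probes do change. Across probes, which are not independent replicates, the fold changes correlated at 0.497, where the simulations had a median of 0.560, and over the brighter 50% of the probes at 0.223 against 0.574. Their covariance was 0.139 over all probes, against a simulated median of 0.0863 and a range of -0.0958 to 0.359, and 0.026 over the brighter 50%, against 0.0119 and a range of -0.0095 to 0.031. The 3 controls do not give each comparison 2 arrays of its own, and part of any excess may come from the shared controls. With a different single control array for each comparison, over the 6 choices, the covariance averaged 0.0724 (0.0325 to 0.122) over all probes and 0.011 (-0.0207 to 0.0467) over the brighter 50%. The number called in both was 4702 without the lowest 50% of probes, 1792 without the lowest 25%, 3598 with a trended, robust variance, 3108 with the floor, 2335 with array weights and 344 with the control-feature covariate. At an adjusted p under 0.01 it was 115, and with the replicate number as a block, which did not pair the arrays, 0. It was 196, 396 and 2494 without control replicate 1, 2 or 3, 222, 291 and 134 without knockdown replicate 1, 2 or 3, and 285, 239 and 547 without E-cadherin replicate 1, 2 or 3.

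The calls were unevenly spread over the 8 ID prefixes, whose meaning is not given in the sources used here. Most probes, 93627, begin with hsa_gmr, and 13% of them passed after E-cadherin overexpression, against 3.01% of the 21442 hsa_gci probes, 11.6% of 13064 hsa_gmi, 9.38% of 9577 hsa_bmr, 8.30% of 1614 hsa_bmi, 5.19% of 11917 hsa_bnc, 5.42% of 12539 hsa_gnc and 4.65% of 172 hsa_bpr probes. Brightness differed in the same way: 64.8% of hsa_gmr but 13.1% of hsa_gci probes lay in the brighter 50%. Against random probes of equal brightness (10000 draws), hsa_gmr still had more rises, 5750 against 5505 (95% of draws 5432 to 5578), and more falls, 6418 against 5962 (5884 to 6040). The draws treat probes as independent, which neighbouring IDs are not (their E-cadherin fold changes correlated at 0.514 over consecutive pairs), so these ranges are too narrow. Without E-cadherin replicate 3 the spread of calls over the prefixes narrowed. Calls went from 618 to 1036 for hsa_bnc, 680 to 1071 for hsa_gnc, 8 to 18 for hsa_bpr and 645 to 1509 for hsa_gci. Those for hsa_bmi and hsa_bmr also increased. Calls decreased from 12168 to 11365 for hsa_gmr and from 1518 to 1483 for hsa_gmi. In the fit on all 9 arrays, the only one compared with draws, the hsa_gci calls after E-cadherin overexpression had fewer falls than equally bright probes but not more rises. Of their 645 calls, 465 rose (72.1%, against 47.4% of all calls) and 180 fell, where equally bright probes gave 488 rises (449 to 528) and 579 falls (536 to 621). After EGFR knockdown 33 hsa_gci probes rose and 20 fell, against 24.2 (16 to 33) and 64.4 (50 to 79) at equal brightness, while 32 hsa_bnc probes rose and 29 fell, against 16.5 (9 to 25) and 44.1 (32 to 57). That excess of hsa_bnc rises over falls turned with the control-feature covariate (15 rose, 19 fell) and without E-cadherin replicate 3 (20 rose, 24 fell). The share of rises there, 44.1% and 45.5%, stayed above that of all knockdown calls, 29.9% and 32.8%. The excess remained with the floor (80 rose, 60 fell), without control replicate 3 (253 rose, 66 fell) and without both arrays (183 rose, 66 fell). As a set, hsa_gci shifted upwards against the other probes in limma's camera with a preset correlation of 0.01, with adjusted p = 0.026 after E-cadherin overexpression and 0.014 after knockdown. With an estimated correlation camera gave adjusted p = 0.61 and 0.46. The test fry, which sets a prefix against no change and not against the other probes, gave adjusted p = 0.11 and 0.33. No other prefix passed in any comparison with camera, and none with fry. Over all probes component 1 moved with the DarkCorner level, as described above, and whether background bears on the prefixes was not tested. With the leading component of the control features as a covariate, 757 of 1023 hsa_gci calls rose after E-cadherin overexpression, and 8 of 24 after knockdown. Falls then outnumbered rises among the hsa_gci knockdown calls, as among all knockdown calls (161 rose, 377 fell). The median hsa_gci log2 fold change after knockdown stayed positive there, at 0.041 against -0.017 for all probes. Without control replicate 3, 356 of 425 hsa_gci knockdown calls rose, and without E-cadherin replicate 3, 1201 of 1509 E-cadherin calls did. Between the treated groups hsa_bnc, hsa_gnc, hsa_bmi and hsa_bmr leaned downwards with E-cadherin. They had 196, 256, 54 and 497 rises, where equally bright probes gave 394, 433, 92.2 and 549, and 519, 541, 119 and 586 falls, where equally bright probes gave 382, 416, 85.6 and 502.

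**Figure D4:**
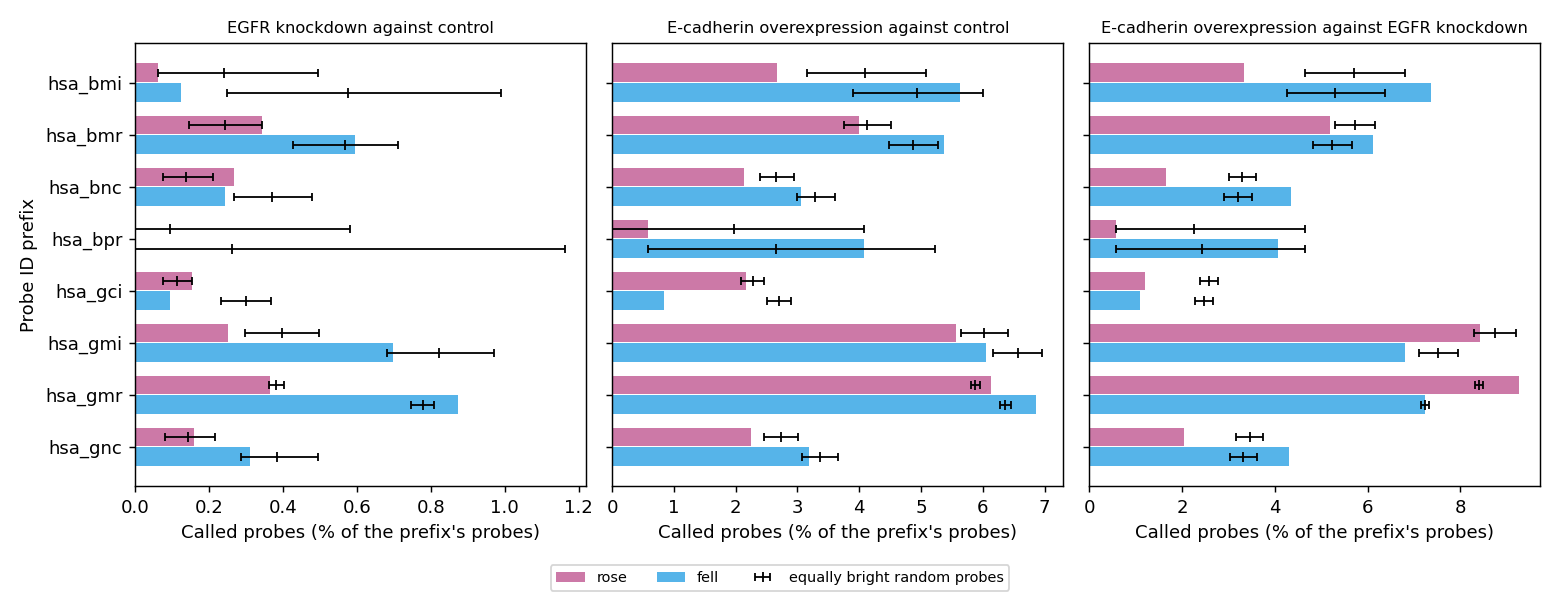
Share of each prefix's probes that rose or fell with an adjusted p under 0.05, by comparison (bars). Black marks show the mean and the range of 95% of 10000 random draws of equally bright probes; hsa_gci falls stay below that range in all 3 comparisons.

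Among all features, 4 array control features carried the name of a human gene. GAPDH and PGK1, both enzymes of glycolysis, are each represented by a feature ending in 3 and one ending in 5. Human-PGK1_3 read 15.21 ± 0.08 in controls, 14.97 ± 0.05 after EGFR knockdown and 14.99 ± 0.05 with E-cadherin (n = 3 each, exact permutation p = 0.1 for each treated group, the smallest that 3 against 3 arrays allow, two-sided). Human-PGK1_5 read 11.19 ± 0.01, 11.21 ± 0.04 and 11.31 ± 0.09 in the same order (exact permutation p = 0.4 and 0.1). Human-GAPDH_3 read 16.55 ± 0.25, 16.30 ± 0.01 and 16.50 ± 0.07 (exact permutation p = 0.4 and 0.8), and Human-GAPDH_5 read 15.24 ± 0.11, 15.13 ± 0.06 and 15.18 ± 0.01 (exact permutation p = 0.3 and 0.4). Over the 68 control features 0 passed in limma after adjustment in any comparison (4, 10 and 7 at an unadjusted p under 0.05 for knockdown, E-cadherin and the direct comparison), so none of these differences passed that test. The Human-PGK1_3 differences from control were -0.24 and -0.22 (log2, SE 0.07), with adjusted p = 0.56 and 0.28.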

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

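The control-feature covariate, the floor at the negative controls and the joint removal of control replicate 3 and E-cadherin replicate 3 were chosen only after the data were seen. Of 69 counts under the alternatives other than leaving out 1 array and the normalizations that moved nothing, 30 stayed within 1.5 times of the main count, and no probe named in the report changed direction under any alternative. The 8 values named for E-cadherin overexpression, against control or against knockdown, kept their side of the threshold throughout. The 4 named knockdown probes lost it in 3 to 12 of their 19 to 21 alternatives, with adjusted p up to 0.127. A repeated quantile normalization and an equal 75th percentile moved almost nothing, since the columns already share 1 distribution, and so say nothing about stability. In what follows, counts are given as EGFR knockdown, E-cadherin overexpression, the direct comparison, and called in both, where they moved. Leaving out the lowest 25% of probes gave 3549 knockdown calls and 1792 in both. Leaving out the lowest 50% gave 10108 and 4702, of which 1332 and 726 were also main calls, while calls of at least 2-fold fell to 1988 for E-cadherin and 2649 in the direct comparison; fewer probes were then tested. The trended, robust variance gave 7781 (936 at 2-fold or more) and 3598 in both. Array weights gave 4764 (1084), 27129 (8308), 37462 (8691) and 2335. With only the groups compared, 2 probes passed for knockdown (2 at 2-fold or more) and 8517 for E-cadherin. With the replicate number as a block the counts were 0 for knockdown (0 at 2-fold or more, with 23751 probes at an unadjusted p under 0.05 in limma), 8276 for E-cadherin, 12470 in the direct comparison and 0 in both; the numbers did not pair the arrays, and 2 of the 9 arrays correlated best with an array of their own number. At an adjusted p under 0.01 the counts were 165 (123), 5315 (2046), 7404 (2511) and 115. The control-feature covariate gave 538 for knockdown and 344 in both, of which 457 and 290 were also main calls. The floor at the negative controls gave 5994 and 3108. Removing control replicate 3 and E-cadherin replicate 3 together gave 3429 (1710) for knockdown, 1926 in both and 7657 E-cadherin calls at 2-fold or more. With 1 array left out, the ranges were 184 to 5297 (151 to 1673 at 2-fold or more) for knockdown, 7652 to 17783 (2801 to 8171) for E-cadherin, 9887 to 22423 (3070 to 6373) for the direct comparison, and 134 to 2494 in both. Alternatives on gene level, for the target genes, for the gene lists and for several probes of a gene, and camera on ranks, were not run. The causes of these moves were not tested. Few calls came from the dimmest probes: only 91 of the knockdown calls and 844 of the E-cadherin calls lay in the lowest 25% by mean level, and the reason was not tested.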

Other observations

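Of the tests in this part, those on E-cadherin replicate 3, on control replicate 3 (its label, and the control-feature covariate as a setting), on switching probes and on consecutive IDs were chosen only after the result was seen. Some probes switched from background to a clear signal. After E-cadherin overexpression 6 called probes were at or below the negative controls on all 3 control arrays and at least 8-fold above them on all 3 E-cadherin arrays. In the other direction, and after EGFR knockdown in either direction, 0 called probes met both conditions. Calls also sat mainly among the brighter 50% of the probes, which held 1332 of the 1552 knockdown calls, 13475 of the 16669 E-cadherin calls and 18027 of the 20719 direct calls.

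E-cadherin replicate 3 stood apart from its group over all probes. The tables argue against a mislabelled array: on the brighter 50% of the probes its lowest correlation with its own group (0.621) exceeded its highest with any other array (-0.130) by 0.751. Array background remains a possible explanation, since within groups component 1 fell as the DarkCorner level rose, with r = -0.960. That value includes the deviation of replicate 3 itself. The DarkCorner level was also read after normalization, so it is not an independent measure of background. The deviation of replicate 3 from the mean of replicates 1 and 2 had an SD of 0.939 and 1.43 in the lowest 25% and the next 25% of probes, and 0.293 and 0.128 in the brighter ones, against 0.655, 0.756, 0.251 and 0.104 between replicates 1 and 2. Whether background is the cause stays open, and no biological explanation was tested.

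The number of knockdown calls rose 3.41 times, from 1552 to 5297, when control replicate 3 was left out. Array background as measured by the control features is argued against, since with that covariate the count still rose 4.63 times, from 538 to 2490. A knockdown array labelled as control was checked on an axis from the other controls (0) to the knockdown arrays (1). It was built from separate arrays for axis and reference. Control replicate 3 lay at 0.557 (range 0.453 to 0.702 over 12 choices of arrays), short of the knockdown arrays in every choice. Control replicates 1 and 2 lay at -0.973 (-2.36 to -0.204) and -0.391 (-1.44 to 0.306). For each of these the other controls include replicate 3, so their wide ranges do not measure how precisely replicate 3 is placed. The correlations of control replicate 3 with the knockdown arrays (0.160 to 0.235) lay above those with its own group (0.104 and 0.125). They lay below those among the knockdown arrays (0.489 to 0.675). On component 2 of the brighter probes control replicate 3 lay at 9.19, the other controls at 55.3 and 69.9 and the knockdown arrays at -41.3 to -26.6. The criterion set for the position was met in neither direction, since 0.557 lay under its limit by less than the range over the choices. These values place control replicate 3 between the groups. They do not decide whether it is a knockdown array labelled as control. A batch that the labels do not record, or a real difference between control cultures, may account for the intermediate position and was not tested.

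The fold changes of the comparisons against control went together, with a covariance of 0.139. The value lay below the highest of 100 simulations of unchanged groups, by 0.220 (observed minus highest, -0.220). These simulations thus do not set it apart from an effect of the shared controls. With a different single control array in each comparison, a value computed after the result was seen, the covariance averaged 0.0724 (0.0325 to 0.122 over the 6 choices). Over all probes it thus stayed positive in every choice without a shared control array. Over the brighter probes it averaged 0.011 (-0.0207 to 0.0467), with choices of either sign. Different control arrays still come from the same group and can differ from the treated arrays together. The calculation therefore does not decide how much of the covariance comes from the controls. Whether the covariance that remained exceeds chance was not tested. How far the shared controls enlarge the number called in both between groups that did change was not tested.

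Of 100 drawn splits of the 9 arrays into 3 trios, 3 gave as many probes called in both, the real one included. This share cannot decide whether the overlap is arbitrary, since trios that mix differing groups also have a larger spread. The highest other split gave 5772 with the 3 E-cadherin arrays as the shared reference and control and knockdown arrays mixed in both other trios. That split points to the distance of the E-cadherin group from all other arrays as a structure of the samples, and the splits do not bear on whether knockdown and E-cadherin share a response. For the single comparisons 10 splits are too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls as observed. With the arrays of the group not compared kept in the fit, the real count was 1552 and the highest other 5 for knockdown, 16669 and 11 for E-cadherin, and 20719 and 1042 for the direct comparison; with only the 6 arrays compared the real splits gave 2, 8517 and 19973, and other splits were not run in that fit.

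Probes with consecutive ID numbers changed together. Over 54745 consecutive pairs within a prefix, both in the brighter 50%, the E-cadherin fold changes correlated at 0.514 across probes, against -0.0108 to 0.0108 in 100 random pairings of equal brightness, and the knockdown fold changes at 0.409. If a probe was called after E-cadherin overexpression, the next ID was called in 47.2% of cases and in the same direction in 44.0%, against 10.71% if it was not. This is consistent with the hypothesis that consecutive IDs often target the same transcript, in which case counts of probes overstate the number of transcripts that changed. Neighbouring IDs with a shared design, such as similar base composition, would give the same pattern and were not tested.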
